A study of Pimephales promelas with 12 samples.

How the data were processed

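RNA from larvae of the fathead minnow (Pimephales promelas), a small freshwater fish used in aquatic toxicity testing, was measured on 12 one-colour Agilent arrays in 3 groups of 4. Per the labels' protocols, larvae were held for 48 h without water renewal in water with no NTO (control) or with measured NTO concentrations of 68 or 1040 mg/L, with 10 larvae in each of 4 beakers per treatment. Each sample was total RNA of 4 whole larvae from 1 exposure replicate, labelled with Cy3 from 200 ng. The intermediate concentrations of the dose series were not analysed here.

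The deposited spot intensities were made by the authors with Agilent Feature Extraction 10.7.3.1, per the file headers, which subtracted local background and marked outlier spots, saturated spots and spots well above background; these marks are other columns that the authors deposited with each array. No normalization between arrays is recorded in the headers. The deposited series table holds log2 values whose scale the sources used here do not state. Set against the scanner values, each of its columns matched the log2 processed signal, scaled to the 75th percentile and centred on the median of each probe over the arrays, with Pearson's r across probes from 0.9999 upwards. The column medians of its log2 values for replicates 1 to 4 were -0.04, -0.02, 0.02 and 0.03 in controls, -0.01, 0.02, 0.03 and 0.02 at 68 mg/L and -0.0033, -0.02, -0.05 and 0.02 at 1040 mg/L.

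Each array held 62372 spots, of which 1319 were control spots and 61053 measured 49849 probes. Control spots and outlier spots were left out, the processed signal was put on the log2 scale, the 75th percentile of each array was subtracted and spots of one probe were averaged. Probes well above background on fewer than 4 of the 12 arrays were not tested, which left 41855 probes and removed 7994. No spot was saturated (0 on all arrays). A value of 0 on this scale is a signal equal to the 75th percentile of its array.

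Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 model over all 12 arrays, with the 3 groups sharing 1 estimate of the spread, and p-values were adjusted by the Benjamini-Hochberg method over all probes tested, with a threshold of 0.05. A moderated F-test compared the 3 groups together. All limma tests were two-sided. The number of arrays limits the precision, and with 4 arrays per group the median 95% interval of a change reached 0.43 log2 to either side. Whole profiles were compared by the share of variance lying between groups, with exact permutation of the array labels, one-sided. Where a probe was not well above background on any array of a group, only a lower bound on its ratio was given. That bound set the mean of the brighter group against the mean, over arrays of the dimmer group, of the higher of the probe's signal and the lowest signal of any probe well above background. It allows for the detection floor only and carries the sampling error of both means. Where the probe's own signals in the dimmer group lay above that lowest signal, it equals the estimated fold.

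The files place the arrays on 2 slides, each scanned in its own scan, with 6 of the arrays on each. Slide was therefore also fitted as a block, and each comparison was repeated within each slide. Samples of the 3 groups carry the same replicate numbers, and a fit with the replicate number as a block was run as well.

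Probes are identified by assembly names (8524 CONTIG, 26117 SINGLET, 14498 UF_Ppr_AF and 710 UF_Ppr_AM probes). None (0) matched an entry among the 64593 genes of the reference gene table, and the files do not pair probes with genes. The 24 gene lists fixed before the data were examined could therefore not be tested, and no gene is named. By the rule fixed for that case, at most 2 probes higher and 2 probes lower are named per comparison, those with the smallest p-value, with probes past the threshold taken first. The design, the groups and the alternatives were also fixed before the data were examined, except for an added pair of alternatives. The background correction named in advance called for mean spot signals, and median spot signals were used in their place.

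The procedure was tested on simulated data in which 200 of the 41855 probes differed between 1040 mg/L and control, over 10 runs with the spread of the real arrays. The noise was drawn independently for each probe, so deviations that probes of an array share were left out. The shares called and the false calls hold for that setting. It called 8.2% of the probes changed 1.5-fold, 44.4% of those changed 2-fold, 70.4% of those changed 3-fold and 81% of those changed 4-fold, with 24 false calls over the 10 runs. With slide as a block the shares were 21%, 56%, 80.6% and 87.2%, with 74 false calls. Alternatives covered normexp background correction with an offset of 50, other scalings, other filters on dim probes, other variance models, array weights, slide and replicate blocks, the series table's values, other thresholds and leaving out each array.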

Results

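The series asked how the transcriptome of fathead minnow larvae responded to NTO, a nitrotriazolone used in insensitive munitions, after 48 h at a low and a high concentration. Arrays were available for 4 control samples, 4 samples at 68 mg/L and 4 samples at 1040 mg/L. The 75th percentile of the processed signal ranged from 909 to 1553 between arrays, and 74.9% to 86.3% of the 49849 probes were well above background. Of these probes, 34751 were well above background on all 12 arrays and 4486 on none.

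The first principal component held 36.0% of the variance and separated the 6 arrays of slide 1 from the 6 of slide 2. Slide accounted for 35.2% of the variance (exact permutation p = 0.00216, the smallest that 462 splits allow), and 8108 of 41855 probes differed between slides at an adjusted p under 0.05 by limma, 5770 of them higher on slide 2. The 3 groups accounted for 17.5% of the variance, against a median of 17.4% over 34650 relabellings (exact permutation p = 0.485). With relabelling kept within slides, the exact permutation p was 0.548. Pairs of arrays from the same slide correlated with a median r of 0.983 across probes, both within and between groups, and pairs from different slides with a median r of 0.970 within a group and 0.971 between groups. Controls lay 2 and 2 on slides 1 and 2, the arrays at 68 mg/L 1 and 3, and the arrays at 1040 mg/L 3 and 1.

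**Figure D1:**
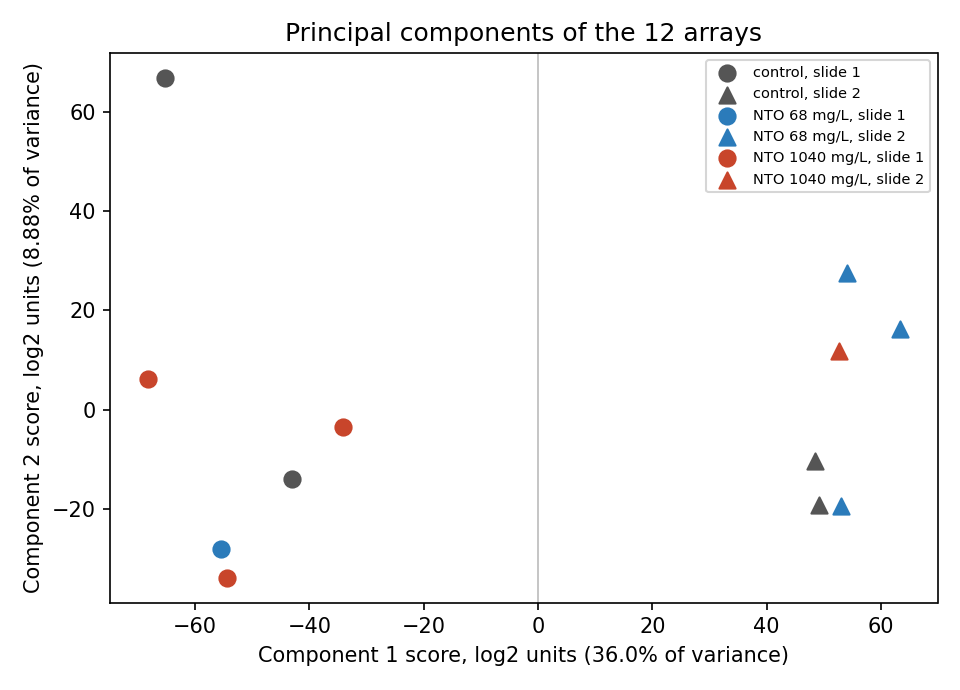
Scores of the 12 arrays on the first 2 principal components of the log2 signals, in log2 units, coloured by group, with circles for slide 1 and triangles for slide 2. The 6 arrays of slide 1 lie below 0 and the 6 of slide 2 above 0 on the first component, and each of the 3 groups has arrays on both sides.

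The comparison of 1040 mg/L with control addressed the response to the highest concentration. The probe CONTIG5615 rose 3.01-fold, from a log2 signal of -3.48 ± 0.16 (SD, n = 4) in controls to -1.89 ± 0.26 (SD, n = 4) at 1040 mg/L. Its log2 change was 1.59 (SE 0.16, 95% interval 1.23 to 1.95, limma adjusted p = 0.0298), and all 4 exposed arrays lay above all 4 controls. The 4 samples at 68 mg/L had a mean of -3.09 ± 0.25 (SD, n = 4), between the other groups. SINGLET_46671 had a log2 signal of 2.65 ± 0.16 (SD, n = 4) in controls and 1.76 ± 0.07 (SD, n = 4) at 1040 mg/L, a log2 change of -0.89 (SE 0.11, limma adjusted p = 0.0984). UF_Ppr_AF_100819 stood at 2.67 ± 0.12 (SD, n = 4) in controls and 1.78 ± 0.05 (SD, n = 4) at 1040 mg/L, a log2 change of -0.89 (SE 0.11, limma adjusted p = 0.0984). UF_Ppr_AF_102651 differed by 0.98 on the log2 scale (SE 0.14, limma adjusted p = 0.280). In all 3 of these probes the 4 arrays of one group lay apart from the 4 of the other, although none passed the threshold.

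CONTIG5615 was the 1 probe of 41855 past the threshold by limma, and 1429 probes had an unadjusted p under 0.05, where 2092.75 would be expected by chance. With slide as a block its log2 change was 1.6 (SE 0.17, limma adjusted p = 0.0692) and no probe (0) passed, with 2006 at an unadjusted p under 0.05, and with array weights no probe (0) passed, with 2331. Within slide 1 the log2 change of CONTIG5615 was 1.65 and within slide 2, with 1 array at 1040 mg/L, it was 1.5. The corresponding changes were -0.88 and -0.88 for SINGLET_46671, -0.87 and -0.86 for UF_Ppr_AF_100819, and 1.00 and 1.17 for UF_Ppr_AF_102651. The call of CONTIG5615 was lost without each of 10 of the 12 arrays in turn, with adjusted p from 0.0734 to 0.216, while over all 12 such fits its log2 change stayed between 1.48 and 1.69. With limma's trend and robust options CONTIG5615, SINGLET_46671 and UF_Ppr_AF_100819 all passed, each with an adjusted p of 0.0154.

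**Figure D2:**
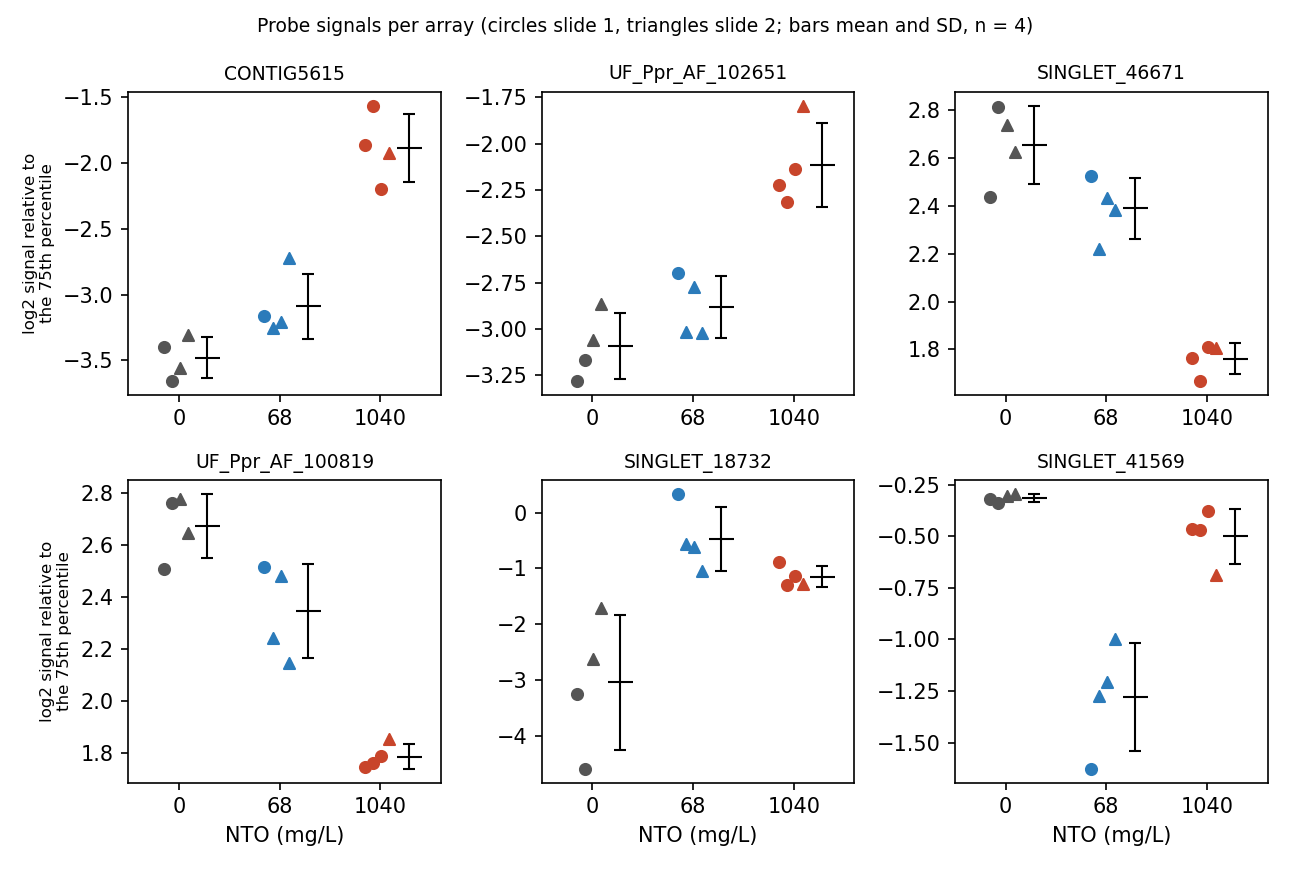
Log2 signal relative to the 75th percentile of the array, by NTO concentration in mg/L, for 6 named probes. Each point is 1 array, circles are slide 1 and triangles slide 2, and bars give the mean and SD of 4 arrays. CONTIG5615 lies between -2.20 and -1.56 at 1040 mg/L, above the controls at -3.65 to -3.30.

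The comparison of 68 mg/L with control addressed the response to the lowest concentration. The probe with the smallest p was SINGLET_41569, with a log2 signal of -0.31 ± 0.02 (SD, n = 4) in controls and -1.28 ± 0.26 (SD, n = 4) at 68 mg/L, a log2 change of -0.96 (SE 0.13, limma adjusted p = 0.595). At 1040 mg/L the same probe stood at -0.50 ± 0.13 (SD, n = 4), nearer to the controls. SINGLET_18732 had the largest difference among the named probes, -3.04 ± 1.21 (SD, n = 4) in controls against -0.47 ± 0.58 (SD, n = 4), a log2 change of 2.57 (SE 0.50, limma adjusted p = 0.998). Its level at 1040 mg/L was -1.15 ± 0.19 (SD, n = 4), so that all 8 exposed arrays lay above all 4 controls. SINGLET_40433 differed by 0.56 (SE 0.12) and SINGLET_2410 by -0.58 (SE 0.12) on the log2 scale, both with a limma adjusted p of 0.998.

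No probe (0) passed the threshold by limma at 68 mg/L, and 1310 had an unadjusted p under 0.05. With slide as a block 0 probes passed and 1599 had an unadjusted p under 0.05, and with trend and robust options 0 passed. The count at an unadjusted p under 0.05 was 3004 without replicate 1 at 68 mg/L, the only array of its group on slide 1, and 2380 with array weights, where 2092.75 would be expected by chance, and 0 passed in both. The log2 change of SINGLET_41569 was -0.98 with slide as a block, -1.30 within slide 1 and -0.86 within slide 2. That of SINGLET_18732 was 2.49 with the block, 4.26 within slide 1 and 1.43 within slide 2. SINGLET_40433 gave 0.53, 0.73 and 0.41, and SINGLET_2410 gave -0.60, -0.59 and -0.58.

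The comparison of 1040 with 68 mg/L asked whether the high concentration differed from the low one. CONTIG5615 was higher at 1040 mg/L by 1.2 on the log2 scale (SE 0.16, limma adjusted p = 0.491), with all 4 arrays at 1040 mg/L above the 4 at 68 mg/L. SINGLET_46671 differed by -0.63 (SE 0.11, limma adjusted p = 0.825). UF_Ppr_AF_107475 differed by 1.4 (SE 0.24, limma adjusted p = 0.825), but it was well above background on 1 of the 4 arrays at 68 mg/L. In replicate 4 at 68 mg/L its log2 signal of -7.05 lay below -6.39, the lowest signal well above background on that array. The size of its difference is therefore uncertain. SINGLET_1632 was well above background on 4 of 4 arrays at 68 mg/L, 2 of 4 controls and 0 of 4 at 1040 mg/L. The bound used for such probes put it 2.1-fold higher at 68 than at 1040 mg/L (limma adjusted p = 0.825). The measured values set that bound, since they lay above the lowest signal well above background. It therefore equalled the estimated fold, with its sampling error, and is not a minimum of the true ratio. The same bound was 1.61-fold within slide 1, 2.05-fold within slide 2 and 1.07-fold with normexp background correction.

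No probe (0) passed the threshold by limma between the concentrations, and 2086 had an unadjusted p under 0.05. With slide as a block 0 passed, with 1711 at an unadjusted p under 0.05, and with trend and robust options 0 passed. The count at an unadjusted p under 0.05 was 5240 without replicate 1 at 68 mg/L, 4476 without replicate 4 at 1040 mg/L and 1378 without replicate 2 at 1040 mg/L. It was 6087 with array weights, and 0 passed in each of these fits. The first 2 of these arrays were each the only one of their group on their slide. They also had the lowest array weight of their group, 0.44 and 0.64. Leaving out or down-weighting them brings this comparison closer to slide 1 against slide 2. The log2 change of CONTIG5615 was 1.23 with slide as a block, 1.29 within slide 1 and 1.14 within slide 2. SINGLET_46671 gave -0.63, -0.78 and -0.54, and UF_Ppr_AF_107475 gave 1.36 with the block and 1.21 within slide 2. Within slide 1 UF_Ppr_AF_107475 was not well above background on the lone array at 68 mg/L, and the bound put it 2.72-fold higher at 1040 mg/L. The measured value of that lone array set the bound, so it is an estimate resting on 1 array and not a minimum. Over all arrays with normexp background correction the log2 difference of UF_Ppr_AF_107475 was 0.43. This comparison is partly confounded with slide, since 3 of 4 arrays at 1040 mg/L and 1 of 4 at 68 mg/L were on slide 1.

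Over the 3 groups together, limma's moderated F-test called 0 probes, with 1507 at an unadjusted p under 0.05. CONTIG5615 had the smallest adjusted p, 0.0805. With slide as a block the F-test called 0 probes, with 1732 at an unadjusted p under 0.05. The count at an unadjusted p under 0.05 was 3039 without replicate 1 at 68 mg/L, 2489 without replicate 4 at 1040 mg/L and 3552 with array weights, with 0 called in each. Both arrays left out there were alone in their group on a slide and had the lowest array weight of their group. Without replicate 4 at 68 mg/L the F-test called 1 probe.

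Probes well above background on every array of one group and on none of the other were few. For 1040 mg/L against control, 1 such probe was detected at 1040 mg/L alone and 13 in controls alone. Of the 35 splits of these 8 arrays, the real one counted here and below, 17 gave as many. For 68 mg/L against control the numbers were 0 and 10, with 20 of 35 splits as large, and for 1040 against 68 mg/L they were 0 and 13, with 23 of 35 splits as large. The bounds for the 13 probes detected in controls and not at 1040 mg/L had a median of 1.51-fold. Measured values set the bound of the median probe, SINGLET_11999. This median is therefore an estimated fold and not a minimum of the true ratio.

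The log2 changes at 68 and at 1040 mg/L, both taken against the same controls, correlated across the 41855 probes with r = 0.280. Simulated arrays with unchanged groups, their shared controls simulated as well, gave 0.229. Probes are not independent replicates. The covariance was 0.0246 against a simulated 0.0215 (SD 0.00172 over 100 simulations). The simulated noise was independent between probes, so that SD leaves out deviations that probes of an array share, and the gap cannot be judged by it. With slide as a block the correlation was 0.457 against a simulated 0.427. When the controls were split so that each concentration had its own pair, the correlation averaged -0.155 over 6 splits. It lay between -0.141 and -0.048 in the 4 splits that gave each concentration 1 control of each slide, and reached -0.501 in the split that gave 1040 mg/L both controls of slide 2. No values without change were simulated for split controls. Most arrays at 1040 mg/L lay on slide 1 and most at 68 mg/L on slide 2, so a slide difference alone would give a negative correlation. The negative sign therefore cannot be read as opposed responses.

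The intervals were wider for dim probes. The 95% interval of the change at 1040 mg/L lay within 2-fold of no change for 81.7% of probes, for 58.8% in the dimmest of 4 equal classes by signal and for 94.7% in the brightest. At 68 mg/L against control it did so for 81.4% of probes, and for 1040 against 68 mg/L for 79.0%. Probes whose 4 values in one group did not overlap the 4 in the other numbered 918 (2.19%), 772 (1.84%) and 946 (2.26%) in the comparisons of 1040 mg/L with control, 68 mg/L with control and 1040 with 68 mg/L, where chance gives 2.86% for exchangeable arrays. Other splits with the slide layout of the real groups, computed after these counts were seen, gave medians of 1.82%, 1.86% and 2.56%. With the real split counted, 9 of 30, 16 of 30 and 11 of 16 splits gave as large a share.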

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

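The tests of replicate number and of dose for the separation of the arrays, the test of slide for the probes at 1040 mg/L, and the splits that kept the slide layout were chosen after those results were seen; the others were not. Dixon's test was run on 54 sets of 4 arrays and marked 5 values, on 4 arrays, as far from the rest of their group, where chance would mark about 2.7.

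Among the arrays at 68 mg/L, replicate 1, the only one on slide 1, had a spike-in slope of 0.901 against 0.953 to 0.960, and a first-component score of -55.6 against 53.03 to 63.3. Among those at 1040 mg/L, replicate 4, the only one on slide 2, had a net negative-control signal of 67.2 against 43.2 to 45.5. Control replicate 2 had a second-component score of 66.9 against -19.4 to -10.3 in the other controls. CONTIG5615 had a log2 signal of -2.72 in replicate 4 at 68 mg/L, against -3.25 to -3.16 in the others of that group.

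The first principal component separated the arrays into sets of 6. All 12 arrays lay with their slide, including those whose slide differed from that of arrays with the same replicate number, which argues against the replicate number. Each of the 3 groups had arrays on both sides, which argues against dose. Among the brightest of 4 equal classes of probes slide held 39.2% of the variance, above the highest other of 462 splits at 27.6%, so low signal over background is not the whole source. A difference in hybridisation or scanning between the slides may remain, and slide and scan cannot be told apart because each slide had its own scan.

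At 1040 mg/L, over the 3 probes with the smallest p (CONTIG5615, SINGLET_46671 and UF_Ppr_AF_100819) and both slides, the lowest within-slide change was 0.947 of the pooled change. A difference between slides alone would give no change within a slide, although choosing probes by the smallest p over both slides favours such closeness. The spots of SINGLET_46671 and UF_Ppr_AF_100819 lay 56 rows and 1 column apart, and the 55 other probes with a single spot in those 2 columns between them had a median log2 change of -0.0353 (95% interval -0.12 to 0.06), which argues against a local defect of the array surface, or one along the columns, for that pair. Chance could not be excluded for the single call. With the real split counted, 4 of the 35 splits of these 8 arrays gave at least 1 probe. So did 3 of the 30 splits with the slide layout of the real groups, with a highest other of 2 in both. A response to NTO remains a hypothesis for these probes.

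Splits say nothing about chance for the other counts, since the real groups gave 0 probes and every split gives at least that: 35 of 35 at 68 mg/L against control, 35 of 35 for 1040 against 68 mg/L and 100 of 100 drawn for the F-test. The highest other counts were 2, 3542 and 3. The split with 3542 probes put all 4 arrays of slide 1 in one group, a structure that follows the slide, and with slide as a block the real groups of that comparison gave 0.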

How the results depend on the processing

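The fit that combined slide as a block with trend and robust options was chosen after the data were seen. So was a fit without probes bright on at least 1 array and not well above background on at least 1 other. Bright meant no more than 4-fold below the 75th percentile, and this rule is wider than that for the 42 probes described below. That fit kept the call of CONTIG5615 at 1040 mg/L against control (limma adjusted p = 0.0280). At 1040 mg/L against control, where 1 probe passed, normexp gave 3 (CONTIG5615, SINGLET_46671 and UF_Ppr_AF_102651), trend and robust 3, slide 2 alone 3, and slide as a block with trend and robust 4 (CONTIG5615, SINGLET_46671, UF_Ppr_AF_100819 and UF_Ppr_AF_105148, the last named after its values were seen). It was 0 with only the groups compared, slide as a block, slide 1 alone, array weights or an adjusted p under 0.01, and 0 to 1 without each array. The log2 change of CONTIG5615 was 1.2 to 1.69 over 27 alternatives, with adjusted p from 0.0119 to 1.00. Leaving out arrays, it passed without replicate 4 at 68 mg/L or replicate 3 at 1040 mg/L and not without any other array. At 68 mg/L against control, where 0 passed, slide 1 alone gave 1 and slide 2 alone 5. Between the concentrations slide 1 alone gave 1. The F-test gave 1 with normexp, 1 with probes above background on all 12 arrays, and 0 to 1 without each array. The cause was not tested.

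The correlation of the changes at both concentrations was 0.457 with slide as a block (0.427 simulated without change). With split controls, for which nothing was simulated, it was -0.155 on average (-0.501 to -0.048). Without each array it ran from 0.0681 (without replicate 4 at 1040 mg/L) to 0.425 (without control replicate 4). Replicate numbers did not pair the samples. Deviations of same-numbered arrays from their group means correlated across probes with r from -0.0971 to 0.397. The 8 of 12 pairs over 0.1 all shared a slide. With slide effects removed as well, the range was -0.335 to 0.195. By their deviations from group means, 4 of 12 arrays correlated best, among arrays of other groups, with one of their own number. The replicate block gave 0 probes at 1040 mg/L, and 0 with slide as well, and changed no other call. At an unadjusted p under 0.05 it gave 3734 probes between the concentrations (2086 without it) and 2510 by the F-test (1507). With slide as a block as well these counts were 2064 and 1975, where 2092.75 would be expected by chance. CONTIG5615 lost its call in 17 of 27 alternatives. The other named values had no call to lose, and 4 of their alternatives passed. Of all 322 alternatives 0 reversed. The probes were chosen by the smallest p on these same arrays, which makes reversals unlikely. Low signal limits dim probes most. The gene lists could not be run.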

Other observations

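The test of a shared transcript below was chosen after the values were seen, as were the definition of the switching probes and the count of those that no test covers; the other tests run on those probes were set before their outcomes were seen.

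A set of 42 probes was bright on at least 3 arrays, no more than 4-fold below the 75th percentile, and not well above background on at least 3 others. Their bright arrays were at least 76.0-fold above their dark ones in the median probe, by the bound used for probes not well above background. Choosing bright and dark arrays by their signal builds in much of this gap, and arrays in between were left out of it. SINGLET_45762 and UF_Ppr_AF_103109, named after their values were seen, correlated with r = 0.999 over the 12 arrays, as did CONTIG5887 and SINGLET_46110 at 0.9997. An array counted as on where the probe was well above background and as off elsewhere. All 42 were on and off within at least 1 group, and 37 were on and off within both slides. The rule of at least 3 bright and 3 dark arrays makes such mixing likely in any case, so no conclusion is drawn from these counts. Dose held 15.9% of the on and off variance, against a median of 18.1% over 34650 relabellings (exact permutation p = 0.817, one-sided). Slide held 9.65% against 9.11% (exact permutation p = 0.381, one-sided). Arrays where a probe was dim but well above background counted as on. Both tests therefore bear on detection and not on bright against dark arrays. Of the pairs of these probes lying over 10 rows or columns apart, 16 correlated above 0.95, against at most 1 in 100 shuffles, and replicate spots agreed in 91.7% of the values of the 4 probes that had them. This argues against spot defects as the source of the whole set, but 18 of the 42 probes had such a partner, and for the 23 with neither a partner nor replicate spots spot defects stay open. A candidate explanation is that the pools of 4 larvae differed in transcripts present before exposure, which was not tested.

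SINGLET_45762 and UF_Ppr_AF_103109 were also among the probes that passed within slide 2 alone, lower than control at both concentrations. Slide 2 holds 1 array at 1040 mg/L and slide 1 holds 1 at 68 mg/L, and such a lone array is assumed to vary like the other groups. The other probes that passed within 1 slide, also named after their values were seen, were UF_Ppr_AF_109887 at both concentrations, UF_Ppr_AF_116732 and UF_Ppr_AF_100704 at 68 mg/L on slide 2, and SINGLET_6973 on slide 1, for its lone array at 68 mg/L. SINGLET_45762 was bright on both controls of slide 2 and, at -6.91 and -6.81, dark on both controls of slide 1. On slide 1 both probes were instead bright, at 3.24 to 3.35, on 2 of 3 arrays at 1040 mg/L and on the array at 68 mg/L, so the direction did not hold on that slide.

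SINGLET_46671 and UF_Ppr_AF_100819 may measure one transcript. After group and slide means were removed, their deviations correlated with r = 0.768, above 98.8% of 10000 random pairs of probes of like signal, which falls short of the percentile set for the test and leaves the explanation open. Sequences of the probes were not used here.

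UF_Ppr_AF_110866 had the largest bound at 1040 mg/L, at least 50.7-fold higher in controls, and was one of the 42 switching probes. The bound was at least 31.5-fold without control replicate 2 and at least 153-fold without control replicate 3, whose log2 signal of -5.88 lay far below the other controls at -0.02 to 0.96. That control was level with replicate 4 at 1040 mg/L, at -5.93, the only array of its group on slide 2. At 68 mg/L the probe stood at -1.42 and 1.18 in replicates 2 and 4, and at -8.03 and -5.635 in replicates 1 and 3. The bound therefore does not describe every control. The probe was paired with SINGLET_45559 at r = 0.995.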
